A study of Mus musculus with 14 samples.

How the data were processed

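The libraries were made from poly(A) RNA of collagenase-isolated adipocytes and sequenced on an Illumina instrument, per the labels' protocols. Reads were aligned with TopHat2 2.0.9 to the mouse genome mm10 and gene values were made with Cuffdiff 2.1.1, per the submitters' processing notes. The deposited values are FPKM per gene: the file headers name the library and no unit, and the unit was taken from these tools and from the values, which were not whole and were divided by length (features under 200 bases had by far the highest values). The annotation, strand setting and count normalization were not given in the sources used here. The values cannot be turned into read counts, so depth per library is unknown, no counting error can be given, and precision rests on the spread between replicates. Cuffdiff can list a gene at 0 where its estimate failed, so such genes are described as listed at 0, and no fold is given against a group at 0. A log2 difference of such a gene is set by the pseudocount. Short features and gene families with near-identical copies (ribosomal protein genes and their pseudogenes, immunoglobulin and haemoglobin genes) are uncertain, because length correction or shared reads can set their values.

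Each file held 38553 Ensembl gene identifiers. A symbol was matched to 36638 of them and 1915 kept their identifier. A RefSeq gene class was matched by symbol to 31058 (20651 protein coding, 2379 lncRNA), and coordinates are those of RefSeq on GRCm38.p6, the reference version of mm10. Groups were taken from the sample titles. Brown libraries entered no test.

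For white adipocytes, limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with trend) was run on log2(FPKM + 0.5) of the 12 white libraries, with values scaled as deposited. Genes needed at least 0.5 FPKM in at least 3 of these libraries, which left 14959 genes, 557 of them lncRNAs. The model fitted the means of the 4 groups (8 residual degrees of freedom), and 5 contrasts were taken: diet in each depot, their difference (epididymal minus inguinal, the interaction), and epididymal minus inguinal on each diet. A Benjamini-Hochberg adjusted p under 0.05, two-sided, was a call. Log2 differences are on the log2(FPKM + 0.5) scale, which understates changes of low genes. For Lep an exact permutation test was added.

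The 33 gene lists, fixed before the data were examined, covered adipokines, fat expansion, lipid, mitochondrial, amino acid, cholesterol, insulin, matrix, inflammatory, interferon, stress, hypoxia, antioxidant, clock, patterning and immediate early genes, well-known lncRNAs, and markers of the other cells that a floating layer can carry. Lists with at least 3 members tested were tested by camera with a preset correlation of 0.01 in 3 contrasts (both diet effects and the interaction), with Benjamini-Hochberg adjustment over 96 tests. Camera with an estimated correlation called 0 lists in each contrast (3, 3 and 3 at an unadjusted p under 0.05), and 9, 10 and 3 of the called lists also passed with fry. Fry, which tests whether a list's genes move on balance one way without comparing them with other genes, was an alternative. Results on some single genes, which were kept in every test, are not reported here. For the brown libraries, the median log2 ratio of list members with a mean of at least 1 FPKM was placed among 10000 random lists of the same size drawn from 20 expression bins.

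Genes were named by a rule also fixed then: for each diet contrast, up to 10 each way with the largest log2 difference among calls with a mean of at least 2 FPKM and no overlap between groups (symbols of the Gm or Rik kind only as noncoding genes); up to 5 noncoding genes each way with a mean of at least 1; up to 2 members each way of each list; always Lep, Adipoq, Ucp1, Mest, Fasn and Adgre1; up to 5 each way for the interaction and 8 for depot contrasts; and for brown libraries up to 8 each way with a mean of at least 5 FPKM, here also listed without features under 200 bases. Neighbours of Lep and Crisp1 were named after their values were seen.

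The settings varied were pseudocounts of 0.1 and 1, no filter, a filter of 2 FPKM, TMM factors (trims of 30% and 5%, own code), quantile normalization, only the 2 groups compared, array weights, the replicate number as a block, a fold threshold of 2, and each library left out in turn. Where a library was left out, the shared spread of the 4 groups was used. Alternatives chosen after seeing the data left out inguinal normal-diet replicates 0 and 2, or 1 and 2, or features under 200 bases, used the lymphocyte level as a covariate, or adjusted over lncRNAs alone. Libraries of different groups share replicate numbers, and the labels do not say what a number marks. Deviations from the group means of same-numbered libraries correlated at 0.184, 0.111 and 0.146 for the depot contrast on the high-fat diet. The numbers may therefore pair those libraries. The results are from the fit without pairs. The number as a block over all 4 groups gave 1777 calls against 1587, with 1504 shared.

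The fitting code was tested on simulated data with 200 changed genes among 14959. In the epididymal contrast it recovered 41.8%, 82.1% and 95.5% of genes changed by 1, 2 and 3 on the log2 scale, with 9 false of 162 calls, and in the inguinal contrast 38.8%, 80.6% and 97.0%, with 20 false of 176. Of 200 unshifted lists, 8 and 4 had camera p under 0.05. The simulated noise was independent between genes and had the same spread in all groups. These rates therefore do not carry over to lists of correlated genes or to groups of unequal spread. Other tools were Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.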

Results

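Poly(A) RNA was sequenced from adipocytes isolated by collagenase from 3 fat depots of male C57BL/6 mice on 2 diets. The depots were the epididymal (visceral white), inguinal (subcutaneous white) and interscapular (brown) pads, and the diets were a normal chow and a high-fat diet fed for 16 weeks from weaning at 3 weeks. White pads were digested for 20 min and brown pads for 40 min, after which the floating adipocyte layer was taken. The series holds 14 libraries, 3 for each of the 4 white groups and 1 brown library per diet, each from the pooled tissue of 3 to 5 mice. The series design calls the white libraries biological triplicates. Each library gave an FPKM value (fragments per kilobase of transcript, scaled to the mapped fragments of the library) for 38553 genes. Read depth was unknown, because the low values did not fall into whole-read steps, and between 15399 and 18029 genes lay above 0 per library. Libraries of one white group correlated across genes with Spearman's rho of 0.978 to 0.980 for epididymal high-fat, 0.950 to 0.971 for epididymal normal-diet, 0.961 to 0.965 for inguinal high-fat and 0.851 to 0.901 for inguinal normal-diet libraries (genes are not independent replicates).

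The libraries differed in mitochondrial RNA and in markers of other cells. All 22 mitochondrial tRNA genes were listed at 0 in 8 libraries (all 6 epididymal ones, inguinal normal-diet replicate 0 and the brown high-fat one), while 10 to 19 of them were above 0 in the other 6. The epididymal diet comparison therefore lay within one of these 2 library sets. Mitochondrial mRNA made up 26.8% to 36.8% of protein-coding FPKM in epididymal high-fat libraries and 40.1% to 66.5% in epididymal normal-diet ones, 26.7% to 35.0% and 20.5% to 60.5% in the inguinal groups, and 82.4% and 80.6% in the brown high-fat and normal-diet libraries. Markers of lymphocytes stood high in the inguinal normal-diet group. On a log2 scale centred on the 12 white libraries, the lymphocyte list lay at 3.35, 0.98 and 4.35 in its replicates 0, 1 and 2, and at −0.48 or lower in each of the other 9 white libraries.

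The series title concerns a long noncoding RNA (lncRNA) that acts on leptin, so the leptin gene was examined first. Leptin, the fat-mass hormone encoded by Lep (ENSMUSG00000059201, chromosome 6, 29060221 to 29073876 in GRCm38.p6), rose in both white depots on the high-fat diet. In epididymal adipocytes it rose from 205 ± 12.3 to 1504 ± 148 FPKM (SD, n = 3 each), 7.34-fold, and in inguinal adipocytes from 131 ± 66.0 to 1269 ± 110 FPKM, 9.70-fold. In the single brown libraries Lep stood at 126 FPKM on the normal and 435 FPKM on the high-fat diet. The log2 differences were 2.87 (SE 0.28) and 3.38 (SE 0.28), with limma Benjamini-Hochberg adjusted p of 3.9e-05 and 3.8e-05, and all 3 high-fat libraries lay above all 3 normal-diet ones in each depot. The exact two-sided permutation p was 0.1 in each depot, the smallest that 3 against 3 libraries can give. The 2 diet effects did not differ by the interaction test (log2 −0.51, adjusted p = 0.51).

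Of 6 neighbours of Lep on chromosome 6, chosen after their values were seen, 3 were higher on the high-fat diet in both depots and 3 passed in neither, while 19.5% of all genes were called in each depot. Hilpda (29272488 to 29275449), which encodes a hypoxia-inducible lipid droplet protein, rose from 12.4 ± 4.96 to 57.4 ± 14.9 FPKM in epididymal adipocytes (log2 2.20, limma adjusted p = 0.00058) and from 10.6 ± 2.93 to 30.7 ± 9.06 FPKM in inguinal ones (1.49, adjusted p = 0.0087). Rbm28 (29123573 to 29164724), a gene for an RNA-binding protein, rose from 20.5 ± 6.87 to 53.2 ± 13.4 FPKM in epididymal adipocytes (1.38, adjusted p = 0.024) and from 18.4 ± 9.11 to 48.7 ± 11.3 FPKM in inguinal ones (1.48, adjusted p = 0.018). Calu (29348106 to 29376675), for a calcium-binding protein of the secretory pathway, rose from 67.7 ± 7.47 to 135 ± 11.1 FPKM and from 60.4 ± 23.0 to 108 ± 13.3 FPKM (0.99 and 0.89, adjusted p = 0.0092 and 0.018). Impdh1, which lies among them, had log2 differences of −0.03 in both depots, and Lrrc4 of −0.10 and −0.36 (adjusted p = 0.87 and 0.40). Prrt4 had log2 differences of 0.89 and 0.36 that did not pass (adjusted p = 0.066 and 0.45), the first of which passed without an expression filter (limma adjusted p = 0.042). The Rbm28 call was lost without epididymal high-fat replicates 1 or 2 or normal-diet replicate 0 (limma adjusted p = 0.0898, 0.0822 and 0.0961), and without inguinal high-fat replicates 1 or 2 or normal-diet replicate 0 (0.069, 0.0662 and 0.0608). The inguinal Calu call was lost without high-fat replicate 1 or normal-diet replicates 0 or 2 (0.0757, 0.0659 and 0.0651). Lnclep, a RefSeq lncRNA at 29030954 to 29039527 in GRCm38.p6, 20694 bases before the start of Lep, matched no gene by name and was not analysed here.

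**Figure D1:**
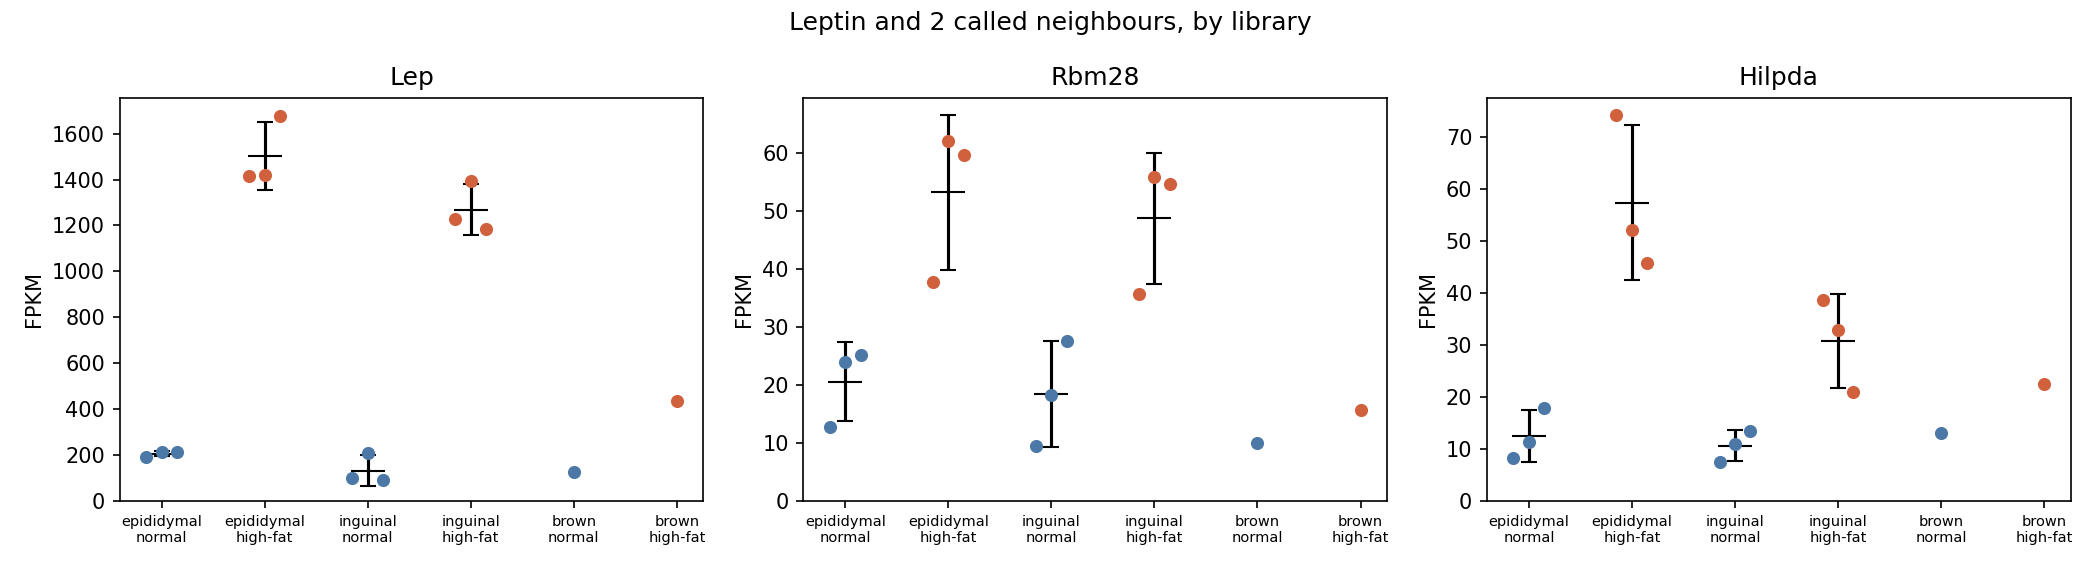
Expression in FPKM of Lep, Rbm28 and Hilpda in each of the 14 libraries, by depot and diet, with mean ± SD for the white groups of 3 libraries. Lep lay between 88 and 213 FPKM in the white normal-diet libraries and between 1184 and 1675 FPKM in the white high-fat ones.

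**Figure D2:**
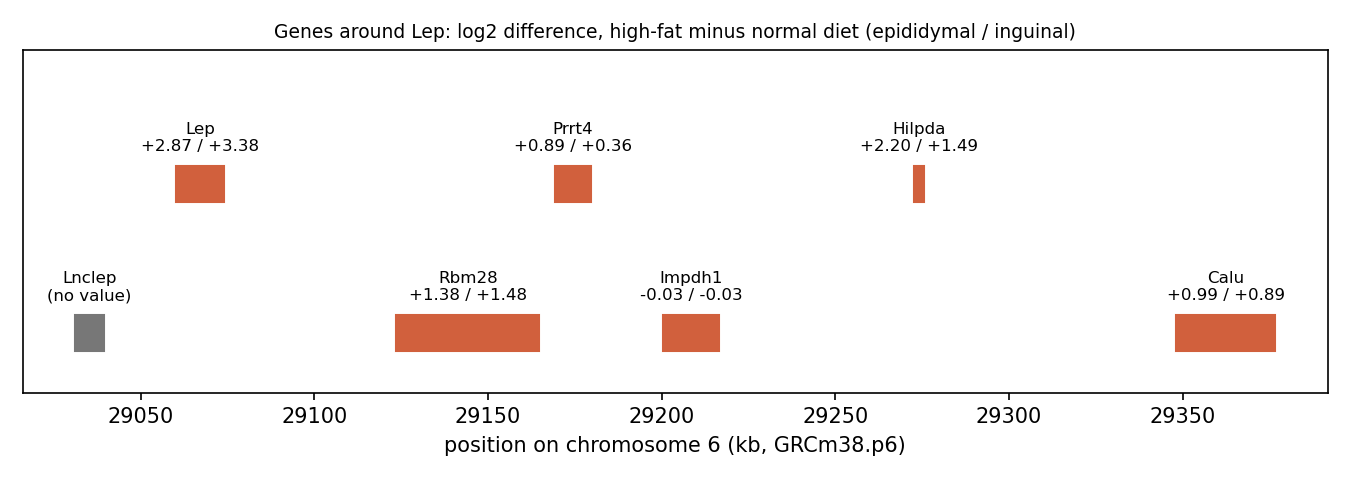
Map of the Lep region of chromosome 6 in GRCm38.p6 to scale, with the log2 high-fat over normal-diet difference in epididymal and inguinal adipocytes under each gene tested and no value for Lnclep; not every annotated gene is drawn. Lep, Rbm28, Hilpda and Calu were higher on the high-fat diet in both depots, and Impdh1 between them was not.

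The diet comparison in epididymal adipocytes asked what 16 weeks of high-fat feeding changed. Among the genes that rose most were genes of lipid-laden macrophages and inflammation. Gpnmb, a transmembrane glycoprotein of such macrophages, rose from 3.94 ± 1.65 to 296 ± 76.8 FPKM (log2 6.11, SE 0.36), Mmp12, the macrophage elastase, from 13.4 ± 2.99 to 387 ± 108 (4.78, SE 0.28), and the neutrophil chemokine gene Cxcl2 from 1.92 ± 1.46 to 102 ± 44.5 (5.53, SE 0.56; n = 3 each). Of 11 endothelial markers 10 fell, with Kdr, the main VEGF receptor, at 4.57 ± 1.77 against 43.4 ± 3.65 FPKM (log2 −3.18, SE 0.26). Of 19 genes of cholesterol synthesis 17 rose, with Dhcr7 at 26.7 ± 1.85 against 3.38 ± 0.418 FPKM (2.81, SE 0.19). By limma with Benjamini-Hochberg adjustment, 2918 of 14959 genes differed, 1818 higher and 1100 lower (1536 and 1346 under quantile normalization, 1214 and 1011 without normal-diet replicate 0), and 2101 of them by at least 2-fold. The 2 groups did not overlap for 2915 of the calls and for 42.4% of all genes tested, against 10% by chance. Without high-fat replicate 0 or 1 the count was 1819 or 1930.

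Other genes that rose most were Ubd, a ubiquitin-like protein gene (log2 5.76, adjusted p = 1.4e-07), Rgs1 (5.57), the macrophage proton pump subunit gene Atp6v0d2 (5.21), Tm4sf19 (5.13) and the leukocyte integrin gene Itgad (4.97). Tph2, for a serotonin-synthesizing enzyme, rose from 0.0811 ± 0.0964 to 29.4 ± 10.3 FPKM, and Slc5a7, for a choline transporter, from 0.461 ± 0.581 to 41.8 ± 5.08. The genes that fell most were Inmt, a methyltransferase gene (116 ± 26.3 to 3.24 ± 1.71 FPKM, log2 −5.03, adjusted p = 2.2e-05), the oestrogen sulfotransferase gene Sult1e1 (29.6 ± 4.38 to 0.464 ± 0.168 FPKM, −4.97), the complement gene C7 (53.4 ± 13.8 to 1.24 ± 0.56 FPKM, −4.97), the enkephalin precursor gene Penk (−4.39), Cyp2f2 (−4.31), Rbp7 (−4.04) and Acsm3 (−4.04). All these calls held with any 1 library left out.

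Cell type markers moved apart in epididymal high-fat libraries. Of 23 macrophage markers tested, 13 were higher, 1 lower and 9 neither (14 and 1 adjusted over the list alone), with a median log2 difference of 1.96 and Adgre1, the F4/80 antigen, at 70.4 ± 21.8 against 12 ± 5.75 FPKM (2.55, SE 0.37, adjusted p = 0.00052). The camera adjusted p was 1.6e-08, and 0.589 with an estimated correlation. Of 11 endothelial markers, 10 were lower, 0 higher and 1 neither (11 lower adjusted over the list alone; median −2.71, camera adjusted p = 4.4e-14, and 0.328 with an estimated correlation). Of 12 fibroblast and preadipocyte markers, 5 were lower, 0 higher and 7 neither (5 lower adjusted over the list alone; median −0.94, camera adjusted p = 0.00031, and 0.589 with an estimated correlation), among them the proteoglycan gene Dcn at 63.0 ± 15.6 against 480 ± 115 FPKM and Ly6a at 31.1 ± 5.23 against 215 ± 54.3. All 5 erythroid genes tested were lower (5 adjusted over the list alone; median −2.89, camera adjusted p = 0.0020, and 0.589 with an estimated correlation).

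Other marker lists did not pass in epididymal adipocytes. Lymphocyte markers had 1 of 14 higher, 1 lower and 12 neither (1 and 0 adjusted over the list alone, median −0.70, camera adjusted p = 0.104). Mural and smooth muscle markers had 1 of 7 higher, 3 lower and 3 neither (2 and 4 adjusted over the list alone, median −1.12, camera adjusted p = 0.1). The pericyte gene Rgs5 was 12.2 ± 2.14 against 88.2 ± 5.9 FPKM and Cspg4 higher at log2 2.18. Mesothelial markers had 1 of 8 lower and 7 neither (1 lower adjusted over the list alone, median −0.15, camera adjusted p = 0.113). Without normal-diet replicate 2 these 3 lists passed, with camera adjusted p of 0.0487, 0.0305 and 0.0419. Skeletal muscle markers had 1 of 6 higher, which was Pvalb, and 5 neither (1 higher adjusted over the list alone, median 0.10, camera adjusted p = 0.469). Too few markers of epididymis and mammary epithelium passed the expression filter to be tested, and Crisp1, a sperm-coat protein gene of the epididymis, was 38.3 FPKM in normal-diet replicate 2 and at most 1.37 FPKM in each other library.

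**Figure D3:**
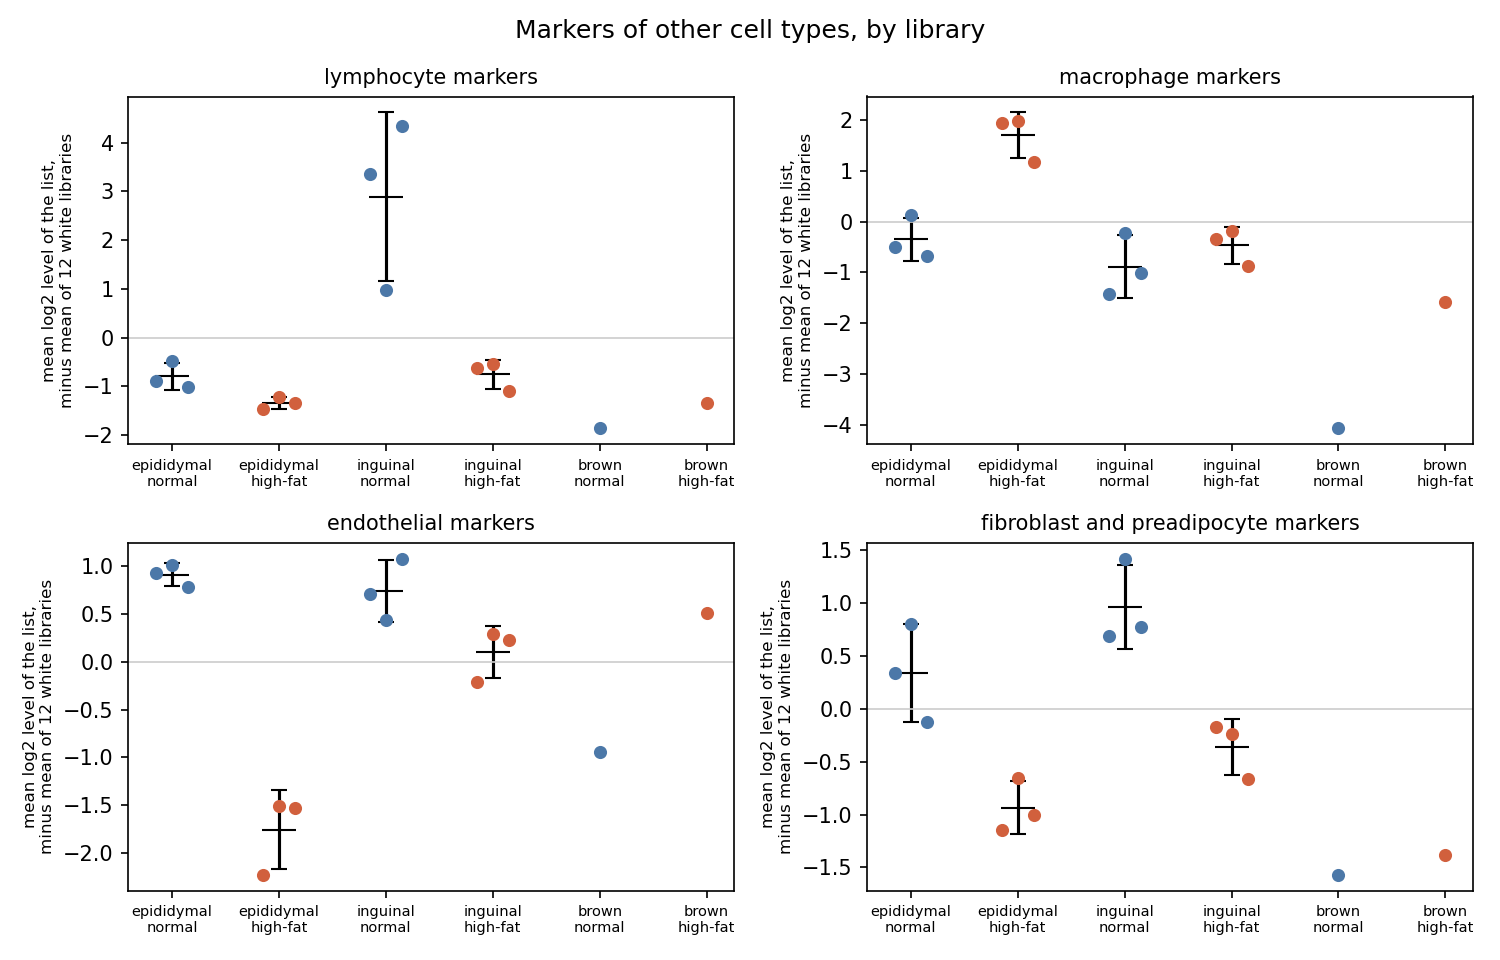
Mean log2 level of lymphocyte, macrophage, endothelial and fibroblast markers in each of the 14 libraries relative to the mean of the 12 white libraries, with mean ± SD for groups of 3. The lymphocyte list lay above 0 only in the 3 inguinal normal-diet libraries, and the endothelial list reached its lowest values in the 3 epididymal high-fat libraries.

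Inflammatory, immediate early and matrix lists were higher in epididymal high-fat libraries by camera, the interferon list was lower, and 3 stress lists did not pass. Macrophage markers rose too, so the lists' cell source stays open. Of 18 genes for inflammatory cytokines and chemokines, 12 were higher, 1 lower and 5 neither (12 and 1 adjusted over the list alone; median 2.43, camera adjusted p = 0.00029, and 0.589 with an estimated correlation). Tnf rose from 0.214 ± 0.0553 to 13.4 ± 6.51 FPKM (log2 4.16, SE 0.42), and Nos2, the inducible nitric oxide synthase gene, fell from 3.71 ± 0.653 to 0.455 ± 0.26 (−2.17). Of 15 immediate early genes, which also respond to tissue dissociation, 8 were higher, 1 lower and 6 neither (10 and 1 adjusted over the list alone; median 1.35, camera adjusted p = 0.00088, and 0.613 with an estimated correlation). Atf3 was 81.0 ± 17.8 against 5.09 ± 1.37 FPKM. Of 23 extracellular matrix genes, 10 were higher, 1 lower and 12 neither (12 and 2 adjusted over the list alone; median 1.33, camera adjusted p = 0.0277, and 0.747 with an estimated correlation), led by the collagen genes Col6a2 (log2 2.79) and Col6a1 (2.60). This list did not pass without normal-diet replicate 2 (camera adjusted p = 0.181). Of 15 interferon response genes, 3 were lower, 0 higher and 12 neither (6 lower and 1 higher adjusted over the list alone; median −0.61, camera adjusted p = 0.0017, and 0.613 with an estimated correlation). Lists that did not pass were the unfolded protein response (3 of 14 higher, 0 lower, median 0.45, camera adjusted p = 0.121), hypoxia (3 of 12 higher, 1 lower, median −0.01, 0.603) and the antioxidant response (3 of 11 higher, 4 lower, median −0.12, 0.269), with the same counts adjusted over the list alone. Ndrg1 of the hypoxia list (log2 −2.37) and the plasma glutathione peroxidase gene Gpx3 of the antioxidant list (−3.46) fell.

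Among metabolic lists, cholesterol synthesis had the lowest p in epididymal adipocytes. Of its 19 genes, 17 were higher, 0 lower and 2 neither (19 higher adjusted over the list alone; median log2 1.5, camera adjusted p = 1.5e-12, and 0.328 with an estimated correlation). Of 10 genes tied to fat expansion, 5 were higher, 1 lower and 4 neither (5 and 1 adjusted over the list alone; median 1.02, camera adjusted p = 0.0109, and 0.642 with an estimated correlation). The Wnt antagonist gene Sfrp5 rose from 23.5 ± 13.9 to 242 ± 73.9 FPKM (3.44, SE 0.53). Mest, an imprinted gene that marks fat expansion, rose from 101 ± 36.0 to 422 ± 72.7 FPKM (2.11, SE 0.52, adjusted p = 0.013), a call lost without high-fat or normal-diet replicate 0 (limma adjusted p = 0.0506 and 0.0574). Of 20 genes of branched-chain amino acid catabolism, 5 were lower, 0 higher and 15 neither (6 lower adjusted over the list alone; median −0.34, camera adjusted p = 0.0030, and 0.734 with an estimated correlation). Acadsb was 38.8 ± 6.57 against 83.3 ± 9.52 FPKM.

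De novo lipogenesis did not pass as a list in epididymal adipocytes, with 6 of 15 genes higher, 1 lower and 8 neither (median 0.47, camera adjusted p = 0.104). Scd2, a stearoyl-CoA desaturase gene, rose from 26.5 ± 9.41 to 236 ± 22.8 FPKM (log2 3.2), and Fasn, the fatty acid synthase gene, from 265 ± 91.1 to 605 ± 146 (1.21, SE 0.29, adjusted p = 0.011; 0.0516 without high-fat replicate 2 by limma), while Acacb fell (−1.79). Fatty acid oxidation had 1 of 18 genes higher and 17 neither (median 0.42, camera adjusted p = 0.104). Without normal-diet replicate 2, camera called both lists (adjusted p = 0.0194 and 0.0439). No called member was found among 12 genes of lipolysis and adrenergic signalling (median −0.23, camera adjusted p = 0.131) or 33 of oxidative phosphorylation (median 0.05, 0.746). Triglyceride synthesis and lipid droplet genes had 3 of 14 higher and 1 lower (median 0.44, 0.131), and fatty acid uptake 4 of 11 higher and 1 lower (median 0.75, 0.132), where Gpihbp1, the capillary anchor of lipoprotein lipase, fell from 214 ± 57.2 to 20.8 ± 10.3 FPKM. The TCA cycle had 1 of 16 higher and 1 lower (median 0.10, 0.906) and insulin signalling 1 of 14 higher and 1 lower (median −0.04, 0.489). Adjusted over the list alone, fatty acid uptake had 5 higher and 1 lower, the TCA cycle had 0 called, and the other lists named here had the same counts.

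The adipokine, adipocyte transcription factor and thermogenic lists did not pass in epididymal adipocytes. Adiponectin (Adipoq) was 1771 ± 506 FPKM on the high-fat and 1915 ± 518 on the normal diet (log2 −0.11, limma adjusted p = 0.88). Of 12 adipokine genes, 3 were higher, 2 lower and 7 neither (4 and 5 adjusted over the list alone, median 0.06, camera adjusted p = 0.81), with adipsin (Cfd) lower at log2 −2.70. The signs of median and camera test differed for adipokines and oxidative phosphorylation, whose medians were above 0 while the test pointed down. Adipocyte transcription factors had 2 of 13 higher and 3 lower (median −0.16, 0.322), and thermogenic genes 6 of 19 higher and 2 lower (median 0.78, 0.131; 8 and 2 adjusted over the list alone, where the transcription factors kept 2 and 3). Ucp1, the uncoupling protein of brown fat, was 0.353 FPKM against 0.0891 (log2 0.50, adjusted p = 0.82). Of 17 depot patterning factors, 6 were lower, 0 higher and 11 neither (6 lower adjusted over the list alone; median −0.67, camera adjusted p = 4.5e-05, and 0.402 with an estimated correlation). Hoxa7 was 2.80 ± 0.669 against 13.4 ± 3.08 FPKM. Of 14 circadian clock genes, 7 were lower, 1 higher and 6 neither (9 and 1 adjusted over the list alone; median −0.88, camera adjusted p = 0.00038, and 0.589 with an estimated correlation). The output gene Hlf was 1.12 ± 0.235 against 4.83 ± 0.583 FPKM.

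In inguinal adipocytes, the diet comparison asked the same. Of 10 fat expansion genes 9 rose, with Mest from 21.1 ± 20.6 to 457 ± 89.4 FPKM (log2 4.82, SE 0.52) and Sfrp5 from 6.54 ± 6.36 to 136 ± 4.30 FPKM (4.66, SE 0.53; n = 3 each). The oxytocin receptor gene Oxtr rose from 1.82 ± 0.791 to 46.9 ± 5.55 FPKM (4.40, SE 0.25), and the network collagen gene Col15a1 from 43.2 ± 12.9 to 278 ± 36.0 FPKM (2.71, SE 0.23). Among the genes that fell most were genes of B and T lymphocytes, with the B cell receptor component gene Cd79a at 2.24 ± 0.631 against 121 ± 88.6 FPKM (−4.96, SE 0.66). By limma, 2914 genes differed, 1391 higher and 1523 lower (1876 and 1511 under quantile normalization), and 2047 of them by at least 2-fold. The 2 groups did not overlap for 2836 of the calls and for 33.1% of genes tested, against 10% by chance. The count was 1863, 1642 and 1776 without high-fat replicate 0, 1 and 2, 4727 without normal-diet replicate 1, and 2023 within one library set, which leaves out normal-diet replicate 0. Without normal-diet replicates 0 and 2, the libraries with the highest lymphocyte levels, it was 999, of which 731 were among the 2914. With only the 2 groups in the model it was 713, and with the lymphocyte level as a covariate 139.

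Genes near 0 on the normal diet were among those that rose most in inguinal adipocytes. Tph2 rose from 0.214 ± 0.302 to 23.3 ± 5.93 FPKM (log2 5.11, SE 0.33, limma adjusted p = 8.6e-06), Itgad from 0.372 ± 0.462 to 27.6 ± 6.96 (5.10), Slc5a7 from 0.0763 ± 0.0661 to 19.3 ± 3.12 (5.10), the gastric lipase gene Lipf from 0.101 ± 0.132 to 13.0 ± 4.12 (4.46) and Mmp12 from 1.5 ± 0.441 to 48.7 ± 12.2 (4.62). Kcnj14 (4.25) and Mrc2 (4) followed. Besides Cd79a, the genes that fell most included the follicular chemokine gene Cxcl13 (−5.04, adjusted p = 0.0019), the light-chain gene Iglc2 (−5.19), Fcmr (−4.89), Ltb (−4.88) and Mup10, a major urinary protein gene (79.7 ± 42.6 to 2.27 ± 1.85 FPKM, −4.88, adjusted p = 0.012). The immunoglobulin variable genes Igkv8-30 and Ighv1-82 were listed at 0 in all 3 high-fat libraries, against 21.4 ± 6.84 and 21.6 ± 14 FPKM. Of the 20 genes ranked by size, all kept their calls without any 1 library, 19 without normal-diet replicates 0 and 2, and 10 with the lymphocyte level as a covariate.

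Markers of other cells differed strongly between the inguinal groups. Of 14 lymphocyte markers, 13 were lower on the high-fat diet, 0 higher and 1 neither (13 lower adjusted over the list alone; median log2 −4.15, camera adjusted p = 6.7e-09, and 0.589 with an estimated correlation). Without normal-diet replicates 0 and 2 the median was −1.92. Of 12 fibroblast and preadipocyte markers, 7 were lower, 0 higher and 5 neither (7 lower adjusted over the list alone; median −1.53, camera adjusted p = 0.00043, and 0.589 with an estimated correlation). The progenitor marker gene Dpp4 was 0.724 ± 0.364 against 10.6 ± 1.18 FPKM. Of 5 erythroid genes, 4 were lower and 1 neither (5 lower adjusted over the list alone; median −3.67, camera adjusted p = 0.0014, and 0.589 with an estimated correlation; median −1.59 without replicates 0 and 2). Of 11 endothelial markers, 2 were lower and 9 neither (2 lower adjusted over the list alone; median −0.61, camera adjusted p = 0.0077, and 0.642 with an estimated correlation), a list call lost without normal-diet replicate 2 (0.0617) or replicates 0 and 2 (0.502). Of 7 mural markers, 3 were higher and 4 neither (3 higher adjusted over the list alone; median 0.83, camera adjusted p = 0.0374, and 0.699 with an estimated correlation), lost without high-fat replicate 1 (0.0694), normal-diet replicate 2 (0.314) or normal-diet replicates 0 and 2 (0.691). Macrophage markers had 6 of 23 higher, 2 lower and 15 neither (7 and 2 adjusted over the list alone, median 0.15, camera adjusted p = 0.104), and passed without high-fat replicate 2 (0.0122) or normal-diet replicate 1 (0.0113). Adgre1 was 12.3 ± 1.51 against 5.76 ± 2.64 FPKM (log2 1.11, limma adjusted p = 0.054; 0.0122 without normal-diet replicate 1). Mesothelial (0 of 8 called, median −0.02, camera adjusted p = 0.703) and skeletal muscle markers (2 of 6 higher, median 0.73, 0.174) did not pass, with the same counts adjusted over the list alone, but the latter passed without normal-diet replicates 0 and 2 (median 0.91, 0.0364).

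Beside these shifts in lymphocyte and stromal markers, several metabolic lists were higher in inguinal high-fat adipocytes. Of 10 fat expansion genes, 9 were higher and 1 neither (9 higher adjusted over the list alone; median 2.00, camera adjusted p = 2.4e-08, and 0.402 with an estimated correlation). Of 19 cholesterol synthesis genes, 13 were higher, 1 lower and 5 neither (16 and 1 adjusted over the list alone; median 1.06, camera adjusted p = 3.7e-09, and 0.328 with an estimated correlation). Hmgcs1 was 209 ± 13.0 against 46.7 ± 28.5 FPKM. Of 18 fatty acid oxidation genes, 11 were higher and 7 neither (12 higher adjusted over the list alone; median 0.91, camera adjusted p = 8.2e-07, and 0.589 with an estimated correlation). Cpt1b, the muscle carnitine palmitoyltransferase gene, was 9.70 ± 5.62 against 0.970 ± 0.902 FPKM. Of 11 fatty acid uptake genes, 6 were higher and 5 neither (7 higher adjusted over the list alone; median 0.71, camera adjusted p = 0.0010, and 0.589 with an estimated correlation). Of 16 TCA cycle genes, 5 were higher, 1 lower and 10 neither (10 and 1 adjusted over the list alone; median 0.56, camera adjusted p = 0.00021, and 0.642 with an estimated correlation). These 5 lists also passed without normal-diet replicates 0 and 2, with medians of 1.44, 0.95, 0.40, 0.45 and 0.23.

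Further inguinal lists passed with all libraries but not without normal-diet replicates 0 and 2. Triglyceride synthesis and lipid droplet genes had 5 of 14 higher and 9 neither (7 higher adjusted over the list alone; median 0.86, camera adjusted p = 0.00031, and 0.642 with an estimated correlation; 0.374 without both). Dgat2 was 1409.8 ± 94.8 against 382 ± 161 FPKM. Adipokines had 5 of 12 higher, 1 lower and 6 neither (6 and 1 adjusted over the list alone; median 0.99, camera adjusted p = 0.0029, and 0.642 with an estimated correlation; 0.22 without both), although Adipoq was 1789 ± 257 against 1309 ± 612 FPKM (log2 0.54, limma adjusted p = 0.31; 0.0369 without normal-diet replicate 1). Oxidative phosphorylation had 3 of 33 higher and 30 neither (0 adjusted over the list alone; median 0.35, camera adjusted p = 0.00043, and 0.699 with an estimated correlation; 0.332 without both). Thermogenic genes had 7 of 19 higher, 1 lower and 11 neither (8 and 2 adjusted over the list alone; median 0.85, camera adjusted p = 0.0274, and 0.613 with an estimated correlation; 0.153 without both), and did not pass without high-fat replicate 2 (0.0822) or normal-diet replicate 2 (0.0602). Ucp1 was 12.5 ± 20.5 against 1.72 ± 1.52 FPKM (log2 0.92, limma adjusted p = 0.60), with 36.1 FPKM in high-fat replicate 2, without which the log2 difference was −0.79. Branched-chain amino acid catabolism had 3 of 20 higher and 17 neither (3 higher adjusted over the list alone; median 0.44, camera adjusted p = 0.0119, and 0.747 with an estimated correlation), lost without normal-diet replicate 0 (0.0612) or 2 (0.154). Extracellular matrix had 10 of 23 higher, 1 lower and 12 neither (10 and 1 adjusted over the list alone; median 0.54, camera adjusted p = 0.0357, and 0.747 with an estimated correlation), lost without high-fat replicate 1 (0.0807) or normal-diet replicates 0 (0.0612) or 2 (0.562).

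Interferon response genes were lower in inguinal high-fat adipocytes, where lymphocyte markers were lower as well. Of 15, 11 were lower, 0 higher and 4 neither (14 lower adjusted over the list alone; median −1.19, camera adjusted p = 6.5e-08, and 0.453 with an estimated correlation). The antiviral gene Mx1 was 0.545 ± 0.0386 against 4.18 ± 0.787 FPKM and Irf7 at 14.7 ± 3.11 against 54.4 ± 14.7. Without normal-diet replicates 0 and 2 the median was −1.60 (camera adjusted p = 8.9e-11). Immediate early genes had 7 of 15 higher, 1 lower and 7 neither (11 and 1 adjusted over the list alone; median 1.31, camera adjusted p = 0.00028, and 0.589 with an estimated correlation; median 0.44 without both). Atf3 was 27.9 ± 3.00 against 3.23 ± 1.06 FPKM. Lists that did not pass were inflammatory cytokines and chemokines (4 of 18 higher, 1 lower, median 0.32, camera adjusted p = 0.223), de novo lipogenesis (5 of 15 higher, 2 lower, median 0.25, 0.132), lipolysis and adrenergic signalling (2 of 12 higher, 1 lower, median 0.19, 0.230), insulin signalling (2 of 14 higher, median 0.19, 0.192) and adipocyte transcription factors (1 of 13 higher, median 0.40, 0.104). Without normal-diet replicate 1, camera called the inflammatory, lipolysis, insulin and transcription factor lists (adjusted p = 0.0486, 0.0305, 0.026 and 0.00333). Neither the unfolded protein response (1 of 14 higher, median 0.26, 0.321), hypoxia (2 of 12 higher, 3 lower, median 0.15, 0.901), the antioxidant response (1 of 11 higher, 2 lower, median 0.07, 0.782), the circadian clock (1 of 14 higher, 1 lower, median 0.19, 0.598) nor depot patterning (3 of 17 higher, 1 lower, median 0.26, 0.173) passed. Adjusted over the list alone, the inflammatory list had 5 higher and 2 lower, lipolysis 3 and 1, transcription factors 0 called, and the circadian clock 1 higher and 0 lower, while the other lists that did not pass had the same counts. The hypoxia list had a mean of −0.03 beside its median above 0. Fasn was 470 ± 102 against 336 ± 65.2 FPKM (log2 0.47, limma adjusted p = 0.26).

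The diet responses of the 2 white depots shared 695 genes higher in both and 283 lower in both, while 83 were called in opposite directions. Independent lists of these sizes would share 169, 112 and 287 genes. Across all 14959 genes the log2 differences correlated with Pearson's r of 0.394 and Spearman's rho of 0.400, over genes that are not independent replicates. The 2 comparisons used different libraries, but same-numbered high-fat libraries of the 2 depots deviated together, so the 2 responses may not be independent. Tph2, Slc5a7, Itgad and Mmp12 rose by 4.62 or more on the log2 scale in each depot.

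The interaction test asked which diet effects differed between the depots. The osteopontin gene Spp1 differed most (epididymal minus inguinal log2 6.10, SE 0.57, limma adjusted p = 0.00099). On the high-fat diet it was higher in epididymal adipocytes and lower in inguinal ones (0.858 ± 0.28 against 8.99 ± 3.74 FPKM in the latter). Lymphocyte genes also had positive differences, with Trac (5.37) and Cd22 (5.27), which fell in inguinal adipocytes, Il7r (5.34), which rose in epididymal ones, and Sema4d (5.23), which did both. Pericyte genes differed the other way, with Rgs5 at −3.94 (SE 0.37), Ndufa4l2 at −4.18, Cox4i2 at −3.61 and Kcnj8 at −3.37. The differences of 1080 genes passed, 718 above and 362 below 0, and 1052 of them were at least 2-fold. Of these, 528 had a diet call in epididymal adipocytes alone, 360 in inguinal ones alone and 157 in both. Quantile normalization, which shifted the median of all genes by −0.17, gave 572 above and 603 below 0, and TMM scaling gave 673 and 519. The count was 433, 446, 592 and 615 without epididymal high-fat replicates 0 or 1 or normal-diet replicates 0 or 2, 672, 597 and 506 without inguinal high-fat replicates 0, 1 or 2, 2627 without inguinal normal-diet replicate 1, and 206 with the lymphocyte level as a covariate. It was 851 without inguinal normal-diet replicate 0, after which each depot lay within one library set, but not the same one.

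Marker lists gave large differences between the depots' diet effects. Endothelial markers had 10 of 11 below 0 and 1 neither (10 adjusted over the list alone; median −2.18, camera adjusted p = 2.6e-11, and 0.352 with an estimated correlation), and mural markers 2 of 7 below 0 and 5 neither (4 adjusted over the list alone; median −1.68, camera adjusted p = 0.0020, and 0.613 with an estimated correlation; 0.0715 without inguinal normal-diet replicates 0 and 2). Macrophage markers had 7 of 23 above 0 and 16 neither (11 adjusted over the list alone; median 1.45, camera adjusted p = 1.2e-06, and 0.589 with an estimated correlation), inflammatory genes 5 of 18 above 0, 1 below and 12 neither (7 and 1 adjusted over the list alone; median 2.07, camera adjusted p = 0.0011, and 0.589 with an estimated correlation), and lymphocyte markers 5 of 14 above 0 and 9 neither (12 adjusted over the list alone; median 3.37, camera adjusted p = 8.2e-07, and 0.589 with an estimated correlation; median 1.12 without both). Depot patterning factors had 6 of 17 below 0 and 11 neither (9 below and 1 above adjusted over the list alone; median −1.30, camera adjusted p = 8.2e-07, and 0.328 with an estimated correlation; median −0.55 without both), with Hoxc8 higher in inguinal high-fat adipocytes (42.4 ± 5.57 against 17.1 ± 3.97 FPKM) and Hoxa5 lower in epididymal ones (1.46 ± 0.249 against 4.86 ± 0.875). Circadian clock genes had 2 of 14 below 0, 1 above and 11 neither (7 and 1 adjusted over the list alone; median −0.84, camera adjusted p = 4.5e-05, and 0.453 with an estimated correlation).

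Most metabolic lists that passed the interaction test with all libraries lay below 0, but most of these calls were lost without inguinal normal-diet replicates 0 and 2, which were rich in lymphocyte markers. Branched-chain amino acid catabolism had 1 of 20 below 0 and 19 neither (1 adjusted over the list alone; median −0.80, camera adjusted p = 6.8e-07, and 0.613 with an estimated correlation). Fat expansion genes had 2 of 10 below 0 and 8 neither (5 adjusted over the list alone; median −1.10, camera adjusted p = 0.00021, and 0.589 with an estimated correlation), and adipokines 1 of 12 below 0 and 11 neither (2 adjusted over the list alone; median −0.63, camera adjusted p = 0.0022, and 0.631 with an estimated correlation). Fatty acid oxidation (18 genes, median −0.58), oxidative phosphorylation (33, −0.35), the TCA cycle (16, −0.52), lipolysis (12, −0.51), adipocyte transcription factors (13, −0.68) and triglyceride synthesis (14, −0.45) passed with no member called, over all genes or adjusted over the list alone. Their camera adjusted p were 0.00078, 0.00042, 0.00031, 0.0109, 0.0129 and 0.0428, and with an estimated correlation the adjusted p were 0.642, 0.699, 0.642, 0.667, 0.699 and 0.747. Without inguinal normal-diet replicates 0 and 2, branched-chain amino acid catabolism (median −0.26, camera adjusted p = 0.0198) and fat expansion (−0.45, 0.0452) passed. Adipokines (0.04, 0.468), fatty acid oxidation (−0.06, 0.345), oxidative phosphorylation (−0.01, 0.230), the TCA cycle (−0.13, 0.0933), lipolysis (−0.04, 0.491), transcription factors (0.15, 0.942) and triglyceride synthesis (0.30, 0.332) did not. Extracellular matrix (1.35, 3.1e-07), the unfolded protein response (0.94, 0.0088) and erythroid markers (−1.31, 0.0264) then passed, and the medians of macrophage markers, inflammatory and interferon genes were 2.40, 3.12 and 1.01. Without inguinal normal-diet replicate 2 alone, lipolysis (0.11), transcription factors (0.108) and triglyceride synthesis (0.457) did not pass. The triglyceride list was also lost without epididymal high-fat replicate 1 (0.0972), epididymal normal-diet replicates 1 (0.0738) or 2 (0.0681), inguinal high-fat replicates 1 (0.0807) or 2 (0.0789) or inguinal normal-diet replicate 0 (0.0662).

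Insulin signalling had 1 of 14 genes below 0 in the interaction test and 13 neither (1 below and 1 above adjusted over the list alone; median −0.53, camera adjusted p = 0.0288, and 0.699 with an estimated correlation), lost without epididymal high-fat replicate 1 (0.0695), inguinal high-fat replicate 2 (0.0583), inguinal normal-diet replicate 2 (0.154) or inguinal normal-diet replicates 0 and 2 (median 0.00, 0.756). Cholesterol synthesis had 3 of 19 above 0 and 16 neither (3 adjusted over the list alone; median 0.45, camera adjusted p = 0.0386, and 0.642 with an estimated correlation). Dhcr7 was 2.27 and Srebf2 at 1.68. It was lost without epididymal high-fat replicate 1 (0.0875), epididymal normal-diet replicate 1 (0.113), inguinal high-fat replicate 2 (0.12) or inguinal normal-diet replicates 0 (0.0697) or 1 (0.157). The interferon response had 3 of 15 above 0 and 12 neither (4 adjusted over the list alone; median 0.48, camera adjusted p = 0.0335, and 0.699 with an estimated correlation), lost with a pseudocount of 0.1 (0.0567) and without epididymal high-fat replicates 1 (0.0809) or 2 (0.057), epididymal normal-diet replicate 2 (0.0674), inguinal high-fat replicate 0 (0.0932) or inguinal normal-diet replicate 1 (0.197). The signs of median and mean differed for fibroblast markers (median −0.38, mean 0.05) and named lncRNAs (0.30, −0.09), and skeletal muscle markers had a median of 0.54 and a test that pointed down. None of these 3 passed (camera adjusted p = 0.754, 0.731 and 0.925; 2, 0 and 0 members above 0 and 0, 1 and 0 below).

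**Figure D4:**
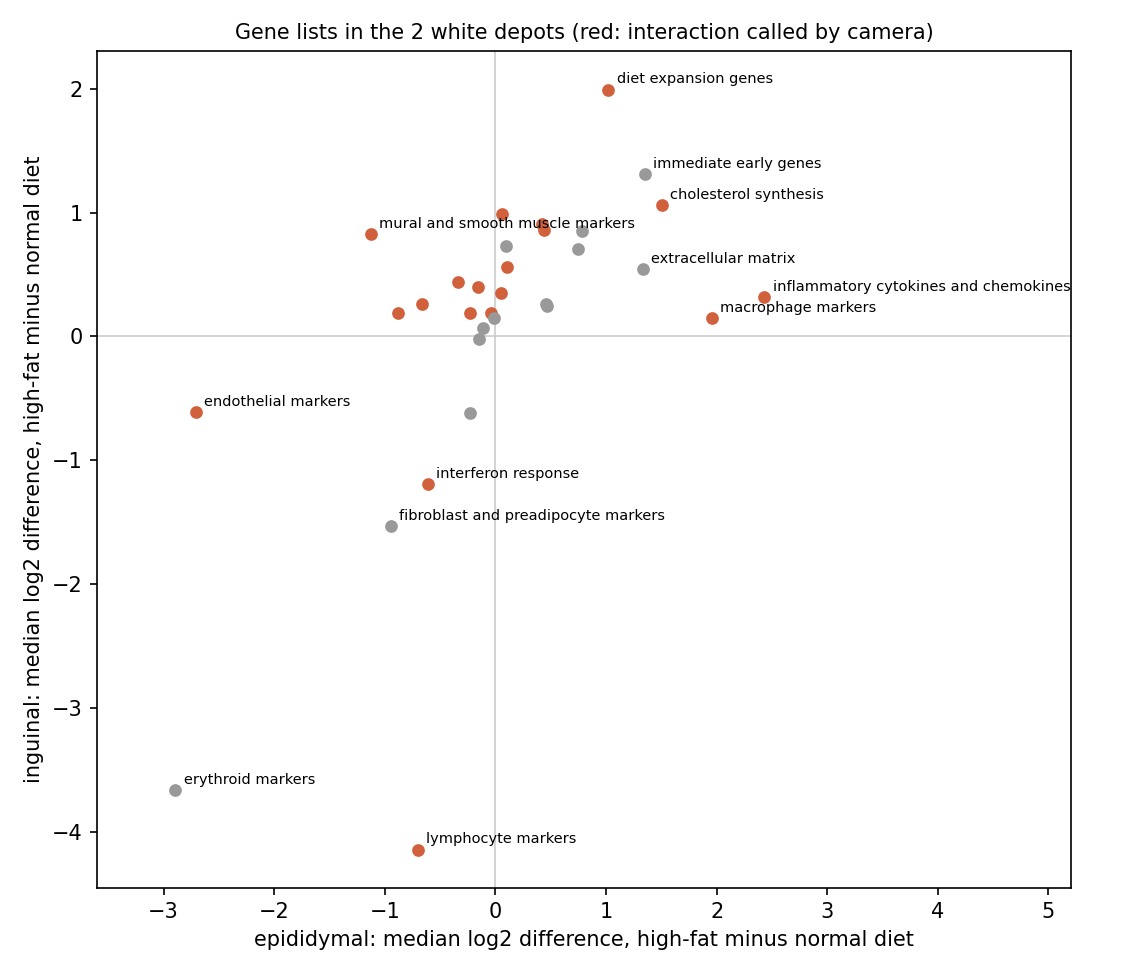
Median log2 high-fat over normal-diet difference of each tested gene list in epididymal (horizontal axis) and inguinal adipocytes (vertical axis), 1 point per list, with the lists that camera called for the interaction in red and those with a median beyond 1.1 in either depot named. Lymphocyte markers lay at −0.70 and −4.15, endothelial markers at −2.71 and −0.61, and cholesterol synthesis at 1.5 and 1.06.

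Long noncoding RNAs were tested as a class because the series concerns them. Gm5627 rose in both depots, from 2.77 ± 0.614 to 17.3 ± 1.38 FPKM in epididymal (log2 2.45, limma adjusted p = 0.0035) and from 1.86 ± 1.65 to 27.9 ± 0.458 FPKM in inguinal adipocytes (3.92, SE 0.48, adjusted p = 0.00041; n = 3 each). Dnmt3aos, named as antisense to a DNA methyltransferase gene, rose in epididymal adipocytes from 0.0645 ± 0.112 to 2.63 ± 0.357 FPKM (2.48, adjusted p = 0.00034). 2010016I18Rik fell there from 6.10 ± 2.79 to 0.39 ± 0.368 FPKM (−2.89, adjusted p = 0.00055), E130102H24Rik from 5.19 ± 2.27 to 0.44 ± 0.262 (−2.54, adjusted p = 0.0024) and Gm454 from 40.2 ± 7.35 to 10.3 ± 3.33 (−1.95, adjusted p = 0.0021). In inguinal adipocytes, Ctcflos rose from 15.7 ± 9.59 to 70.4 ± 5.55 FPKM (2.28, adjusted p = 0.0019), while A630023P12Rik was listed at 0 in all high-fat libraries against 3.25 ± 2.88 FPKM, and AI504432 (−2.68) and AU020206 (−2.48) fell beside the lymphocyte markers. The strand setting was not given in the sources used here, so an antisense gene and its partner could not be separated.

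Of 557 RefSeq lncRNAs that passed the filter, limma called 48 in epididymal adipocytes, 14 higher and 34 lower (15 adjusted over the list alone), and 62 in inguinal ones, 25 higher and 37 lower (42 adjusted over the list alone). The called share was 8.62% and 11.1%, against 19.5% of all genes in each depot, not matched on expression. Whether lncRNAs respond less was not tested. In all, 14 lncRNAs were called in both depots, 12 of them in the same direction, and 8 differed in the interaction test. The epididymal count was 24, 27, 29, 32 and 31 without high-fat replicates 0, 1 or 2 or normal-diet replicates 1 or 2. The inguinal count was 38 without high-fat replicate 1, 41 without normal-diet replicate 0, 113 without normal-diet replicate 1 and 19 without normal-diet replicates 0 and 2. It was 36 with a filter of 2 FPKM, 11 with only the 2 groups in the model and 1 with the lymphocyte level as a covariate. AI662270, at an epididymal log2 difference of 1.58 (adjusted p = 0.011, and 0.0554 by limma without high-fat replicate 1), had an interaction of 3.44. The list of 12 well-known lncRNAs had 2 lower and 10 neither in epididymal adipocytes (2 lower adjusted over the list alone; median −0.23, camera adjusted p = 0.0499, and 0.589 with an estimated correlation), of which Airn fell by 1.92 on the log2 scale. That call was lost with a pseudocount of 1 (0.0508) and without high-fat replicate 2 (0.0869) or normal-diet replicates 0 (0.0537) or 2 (0.0846). In inguinal adipocytes the list had 1 higher, 3 lower and 8 neither (2 and 3 adjusted over the list alone, median −0.62, camera adjusted p = 0.155).

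The depots were also compared on each diet. On the normal diet, epididymal adipocytes were higher in several genes, with the light-chain gene Igkv14-126 at 39.9 ± 14.1 against 3.33 ± 4.52 FPKM (log2 4.21, limma adjusted p = 0.019, lost without epididymal replicate 0 or 2 or inguinal replicate 2), the mesothelial gene Upk3b at 5.45 ± 1.88 FPKM and listed at 0 in all inguinal normal-diet libraries, the serpin gene Serpina3b at 11.0 ± 5.16 against 0.113 ± 0.121 (log2 4.13, SE 0.38) and Ear2 at 33.7 ± 4.62 against 2.66 ± 0.921 (3.46, SE 0.22; n = 3 each). Inguinal adipocytes were higher in several B cell genes, with Ly6d at 77.8 ± 59.9 against 0.612 ± 0.531 FPKM (−5.72, SE 0.77, adjusted p = 0.0025) and Cd79a at 121 ± 88.6 against 1.89 ± 0.698 (−5.17, adjusted p = 0.0019). Fcmr (−5.38), Fcer2a (−5.16), H2-Ob (−5.03) and the CD20 gene Ms4a1 (−4.87) followed. Limma called 974 genes, 353 higher in epididymal and 621 higher in inguinal adipocytes, and 959 of them had no overlap, as did 19.1% of genes tested against 10% by chance. Quantile normalization gave 687 and 621. With only the 2 groups in the model the count was 14, and with the lymphocyte level as a covariate 26, and 6 and 2 of the 16 genes ranked by size kept their calls. The count was 474, 485 and 264 without epididymal replicates 0, 1 or 2, 3092 and 388 without inguinal replicates 1 or 2, 562 without inguinal replicates 0 and 2, and 1097 within one library set, which leaves out inguinal replicates 1 and 2 and shared 595 calls.

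On the high-fat diet, genes higher in epididymal adipocytes included Spp1 (23.9 ± 10.8 against 0.858 ± 0.28 FPKM, log2 4.07, SE 0.41), Gpnmb (296 ± 76.8 against 24.3 ± 3.72, 3.56), the angiotensinogen gene Agt (47.6 ± 27.5 against 3.16 ± 1.70, 3.69) and Bcl2a1b (4.23). The ribosomal protein gene Rpl29 was 127 ± 11.7 against 6.38 ± 2.34 FPKM (4.26, adjusted p = 0.0031). The 8 features that were most strongly higher in inguinal adipocytes were mitochondrial tRNA genes such as mt-Ts1, mt-Te and mt-Tc, which were listed at 0 in all epididymal libraries. Limma called 1587 genes, 1059 higher in epididymal and 528 higher in inguinal adipocytes, with no overlap in any of the 1587 and in 38.4% of genes tested, against 10% by chance. Ribosomal protein genes had 62 of 87 called, 61 higher in epididymal adipocytes, while all other genes outside ribosomal proteins, pseudogenes and features under 200 bases had 1413 of 14280 called (9.90%). The 3 epididymal high-fat libraries belonged to one library set and the 3 inguinal high-fat ones to the other, so library set and depot coincided here. The count was 799 and 783 without epididymal replicates 0 or 1, and 1057 and 817 without inguinal replicates 0 or 2.

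Brown adipocytes had 1 library per diet, so differences between them had no replicate check. Genes of macrophages were higher in the high-fat library, with Cd68 at 33.2 against 0.496 FPKM, Ctss, for a lysosomal protease, at 37.1 against 0.796, Rgs1 at 26 against 0.246 and Cxcl2 at 26.8 against 0.253, while Tyrobp (29.8 FPKM) and Mmp12 (29.1 FPKM) were listed at 0 on the normal diet. Fabp3, the heart-type fatty acid binding protein gene, was 158 against 5.23 FPKM, S100b 33.8 against 0.788 and Ucp1 503 against 121. Lower in the high-fat library were Cyp2e1 (226 against 2481 FPKM), the developmental regulator gene Irx2 (0.385 against 12.3) and Serpina3k (0.255 against 15). Of 7246 genes with a mean of at least 5 FPKM, 570 were at least 2-fold higher and 363 at least 2-fold lower on the high-fat diet. The largest ratios belonged to short features, with Snora65 at 78.8 FPKM against 0 and mitochondrial tRNA genes listed at 0 in the high-fat library. The 2 brown libraries belonged to different library sets, so set and diet could not be told apart.

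List medians of these 2 brown libraries were placed among 10000 random lists matched on expression. Medians stood at or above the 99.5 percentile for macrophage markers (log2 2.79, percentile 100), inflammatory genes (1.75, 100), endothelial markers (1.54, 100), immediate early genes (0.84, 100), extracellular matrix (0.76, 100), the TCA cycle (0.75, 99.97), skeletal muscle markers (1.16, 99.97), fatty acid oxidation (0.65, 99.95), oxidative phosphorylation (0.41, 99.83), thermogenic genes (0.55, 99.57) and mural markers (1.06, 99.5). Medians stood below percentile 1 for de novo lipogenesis (−0.68, percentile 0.06, with 14 of 15 members lower), the interferon response (−0.38, 0.4), insulin signalling (−0.45, 0.5), lipolysis (−0.55, 0.9) and triglyceride synthesis (−0.53, 0.93).

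Brown and white adipocytes were compared by values alone. Ucp1 was 121 and 503 FPKM in the brown normal-diet and high-fat libraries, above the highest white value (36.1). Cox7a1, a cytochrome oxidase subunit gene, was 46.2 and 289, and Cidea, a lipid droplet protein gene, 54.7 and 105. Of 21 thermogenic genes, 15 lay above all 6 white libraries on the normal diet and 2 below, with a median brown minus white log2 difference of 1.63, and on the high-fat diet 16 lay above and 2 below, with a median of 1.28. Muscle genes were also above all white libraries, with the myoglobin gene Mb at 6.93 and 25.9 FPKM and Myl2 at 4.85 and 19.1. In all, 101 genes lay above and 922 below all 12 white libraries.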

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

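All tests of explanations and of other splits of the samples in this part were chosen after the results were seen, while the interaction test was planned. A difference between the diet effects of the 2 white depots (epididymal minus inguinal, log2) drew attention to 1080 genes, 8 of them lncRNAs, and to 19 lists. Camera with an estimated correlation called 0 lists there (3 at an unadjusted p under 0.05), and fry 3. The 19 were endothelial (−2.18), mural (−1.68), macrophage (1.45) and lymphocyte markers (3.37), inflammatory genes (2.07), depot patterning factors (−1.30), fat expansion genes (−1.10), the circadian clock (−0.84), branched-chain amino acid catabolism (−0.80), adipocyte transcription factors (−0.68), adipokines (−0.63), fatty acid oxidation (−0.58), insulin signalling (−0.53), the TCA cycle (−0.52), lipolysis (−0.51), triglyceride synthesis (−0.45), oxidative phosphorylation (−0.35), the interferon response (0.48) and cholesterol synthesis (0.45).

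Vascular and pericyte genes among the named ones were lower in the epididymal effect: Ndufa4l2 (−4.18), Ppp1r14a (−3.99), Rgs5 (−3.94), Cox4i2 (−3.61), Kcnj8 (−3.37), Gpihbp1 (−3.07), Rbp7 (−2.85), Btnl9 (−2.82), Apln (−2.65), Notch3 (−2.55), Kdr (−2.45) and Flt1 (−2.21). The difference for Ppp1r14a did not pass without epididymal high-fat replicates 0 or 1, normal-diet replicate 2 or inguinal high-fat replicates 1 or 2. So were Sult1e1 (−3.02), Mest (−2.71), Gm4876 (−2.64), Nos2 (−2.38), Airn (−2.11), Hlf (−2.10), Hoxa5 (−2.09), Gsta4 (−2.07), Oxtr (−2.01), Hoxa7 (−1.98), Hoxc8 (−1.75), Hoxc9 (−1.75), Ndrg1 (−1.58), Grb14 (−1.42) and Acadsb (−1.19). Lymphocyte and immunoglobulin genes were higher in it: Trac (5.37), Il7r (5.34), Cd22 (5.27), Sema4d (5.23), Ighv1-82 (5.23), Igkv8-30 (4.60), Fcmr (4.49), Igkv6-15 (4.16) and Ltb (3.89). Also higher were Spp1 (6.10), Gpnmb (3.90), AI662270 (3.44), Rgs1 (3.23), Ccl5 (3.16), Tnf (3.11), Epsti1 (2.98), Tm4sf19 (2.84), A630023P12Rik (2.64), A530040E14Rik (2.56), Dpp4 (2.56), Cd74 (2.47), Ubd (2.31), Dhcr7 (2.27), Sdf2l1 (2.04), Mx1 (1.93), Srebf2 (1.68) and Slc2a1 (1.5). Ighv1-82, Igkv8-30, Igkv6-15 and A630023P12Rik were listed at 0 in inguinal high-fat libraries, and their values are set by the pseudocount. In brown adipocytes the median of triglyceride synthesis genes (−0.53) went against the inguinal one, and that of endothelial markers (1.54) against both white depots, differences that were not tested.

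Other splits of the same libraries were fitted to see whether chance can be excluded. For the interaction, 2 of 100 splits drawn from 200 gave at least 1080 genes, the real one included. This says nothing about chance, because splits that mix the diets put the diet effects into the spread and no split stands for equal diet effects in both depots. The other, with 4474 genes, swaps diets within the inguinal libraries, which turns the diet effect shared by both depots into the difference. For each other contrast 10 splits are too few for a share under 0.05. Those that mix its groups also put its difference into the spread, so low counts there say nothing about chance. The real split gave 2918 epididymal and 2914 inguinal diet calls, and another at most 1 and 6. Depot calls were 974 and 1587 (normal and high-fat diet) against 367 and 1, and lncRNAs 48 and 62 against 0.

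The lymphocyte markers of the inguinal normal-diet libraries were weighed first. Of 15 measured markers of B and T cells, 13 lay above each of the other 9 white libraries in all 3, so lymphoid tissue carried over, such as from the lymph node within the inguinal pad, is a candidate explanation. Blood as the only source is argued against by a comparison with epididymal normal-diet libraries. The lymphocyte level was 3.69 higher (log2, spread 1.75) than there, while the erythroid level was 1.12 lower (difference −1.12). Within inguinal normal-diet replicates 0, 1 and 2, however, erythroid levels (0.86, −0.94 and 3.19) ranked as the lymphocyte ones did (3.35, 0.98 and 4.35). Inguinal high-fat libraries had erythroid levels of −3.37, −1.78 and −2.24, so a share of blood stays open. The library set is argued against because the lowest of the 3 libraries, which come from both sets, stood 1.46 above the highest other white library. A difference in lymphocytes between diets in the pad itself stays open.

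In epididymal high-fat libraries 10 of 11 endothelial markers fell and 13 of 23 macrophage markers rose, list calls that were lost with an estimated correlation (camera adjusted p = 0.328 and 0.589). A lower share of every other cell type is argued against by medians 4.66 apart on the log2 scale (SD of members 1.88 and 0.57). Scaling is argued against by an endothelial median of −2.80 or lower and a macrophage median of 1.80 to 1.87 under TMM factors and quantile normalization. With a fibroblast median of −0.94 and a mural median of −1.12, fewer vascular and stromal cells per adipocyte cannot be told apart from lower expression within them, as no cell counts were used here. A response of these cells to the diet stays open.

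The depot contrast on the high-fat diet coincided with the library sets. A shift between sets would recur on the normal diet between epididymal libraries and inguinal replicates 1 and 2. The calls' differences were smaller there by a median of 1.36 (log2, SD 0.35) for ribosomal protein genes, 0.65 (SD 1.3) for pseudogenes and features under 200 bases and 1.28 (SD 1.02) for all other genes, and by 0.76, 0.47 and 1.27 against replicate 1 alone. Genes called for a large high-fat difference would differ less elsewhere in any case, replicate 2 was rich in lymphocyte markers, and replicate 1 is a single library. Of the ribosomal calls, 98.4% shifted the same way in replicate 0, which belongs to the epididymal set (51.8% for all other genes). Set and depot therefore cannot be told apart for any of these parts, and depot stays open as a biological explanation.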

How the results depend on the processing

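Leaving out 2 libraries or features under 200 bases, the lymphocyte covariate and adjustment over lncRNAs alone were chosen after the results were seen. Lep kept its direction and call in both white depots under every alternative run, with log2 differences of 2.68 to 2.91 in epididymal and 2.11 to 3.76 in inguinal adipocytes. For 248 other results on single genes, 3886 of 4388 comparisons with an alternative kept direction and side of the threshold, 457 (132 results) lost the call, 10 (3 results) gained it and 35 (21 results) changed sign. For 96 results on lists, 1114 of 1312 kept the direction of the test and its side of the threshold, 134 lost the call, 16 gained it and 48 (23 results) changed the direction of the test, 29 of them (19 results) with the sign of the median. Read depth is unknown, so what it limits could not be stated. The lone inguinal normal-diet library left without replicates 0 and 2 was assumed to vary like the other groups.

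Counts of calls moved as follows where they moved by over 1.5 times, and the cause was not tested. Array weights gave 5110 genes in the epididymal and 4612 in the inguinal diet contrast, 2836 for the interaction, 2098 and 3681 for the depot contrasts on normal and high-fat diet, and 129 epididymal lncRNAs. With only the 2 groups compared in the model there were 713 inguinal diet calls, 14 and 2993 depot calls on normal and high-fat diet, and 84 epididymal and 11 inguinal lncRNAs. Without an expression filter the interaction had 695 calls and the normal-diet depot contrast 577. A filter of 2 FPKM left 36 inguinal lncRNAs, and adjustment over lncRNAs alone 15 epididymal ones. Without inguinal normal-diet replicates 0 and 2 there were 999 inguinal diet calls, 562 normal-diet depot calls (247 shared with the 974), 19 inguinal lncRNAs and 11 inguinal lists. With the lymphocyte level as a covariate there were 139 inguinal diet calls, 206 interaction calls, 26 normal-diet depot calls and 1 inguinal lncRNA. This covariate nearly follows inguinal diet, so it also removes diet differences. Leaving out 1 library gave 1819 to 2323 epididymal and 1642 to 4727 inguinal diet calls, 433 to 2627 interaction calls, 264 to 3092 and 783 to 1076 depot calls on normal and high-fat diet, and 24 to 34 epididymal and 38 to 113 inguinal lncRNAs. The 14, 18 and 19 lists called by camera for epididymal diet, inguinal diet and interaction became 0, 0 and 0 with an estimated correlation and 9, 10 and 3 with fry. The median brown minus white difference of thermogenic genes was 2.78 on normal and 1.85 on high-fat diet with a pseudocount of 0.1, and 2.03 on normal diet with TMM factors.

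The replicate number as a block gave 3404 epididymal and 3453 inguinal diet calls, 1152 interaction calls, 1085 and 1777 depot calls on normal and high-fat diet, 55 and 66 lncRNAs, and 14, 17 and 18 lists. The pairing check gave correlations of 0.18, 0.0825 and 0.162 for epididymal diet. They were 0.272, 0.0982 and 0.00688 for inguinal diet, and 0.133, 0.0288 and 0.0761 for the normal-diet depot contrast. The epididymal diet values were close to those of the high-fat depot contrast (0.184, 0.111 and 0.146). These correlations therefore do not settle what a number marks. In the epididymal diet contrast every library correlated best with its own number, a hint from the data and not from the design. Under the block, extracellular matrix in inguinal adipocytes (camera adjusted p = 0.0658) and cholesterol synthesis in the interaction (0.0641) were not called, Adgre1 in inguinal adipocytes was (limma adjusted p = 0.0145), and no other list call changed.

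List tests changed direction and genes changed sign as follows, and the cause was not tested. Lists whose median alone changed sign are left out. Fry pointed the other way than camera, at the same median, for epididymal adipokines (0.059) and oxidative phosphorylation (0.054) and for fibroblast (−0.38) and skeletal muscle markers (0.54) in the interaction. Without inguinal normal-diet replicates 0 and 2, inguinal medians were −0.22 for lipolysis, −0.19 for branched-chain amino acid catabolism, −0.31 for insulin signalling, −0.37 for transcription factors, −0.17 for extracellular matrix, −0.46 for inflammatory genes, −0.35 for the unfolded protein response, −0.43 for hypoxia, −0.23 for the antioxidant response, −0.073 for the clock and −0.60 for macrophage markers. Interaction medians were then 0.30 for triglyceride synthesis, 0.48 for thermogenic genes, 0.31 for fibroblast and −1.31 for erythroid markers, while the antioxidant response, at −0.070, changed only the direction of its test. Inguinal Adipoq was −0.18, Ucp1 −0.14 and Impdh1 0.21 without both, and Adipoq −0.071 under quantile normalization. With the lymphocyte covariate, inguinal log2 differences were 0.27 for AI504432, −0.15 for Acat1, −0.40 for Acsl1, −0.67 for Adipoq, 0.59 for Cd74, −0.58 for Cxcl1, −0.088 for Dlat, −0.093 for Ndufs1, −0.15 for Fasn and Prkar2b, −0.20 for Fosb, −0.19 for Gm4876, 0.77 for Hba-a2, 0.49 for Impdh1, 0.31 for Mirt1, −0.37 for Pfkfb3, 0.32 for Thy1 and −1.33 for Ucp1. Epididymal Impdh1 was 0.051 with this covariate, inguinal Impdh1 0.088 with array weights and epididymal Lrrc4 0.034 under quantile normalization.

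With 1 library left out, medians ran from −0.18 to 0.13 for epididymal oxidative phosphorylation and −0.041 to 0.19 for the TCA cycle, and in inguinal adipocytes from −0.13 to 0.25 for hypoxia, −0.066 to 0.41 for the antioxidant response and −0.17 to 0.40 for the clock. In the interaction they ran from −0.20 to 0.21 for lipogenesis, −0.43 to 0.058 for thermogenic genes, −0.37 to 0.64 for matrix, −0.25 to 0.42 for immediate early genes, −0.89 to −0.11 for fibroblast, 0.051 to 1.13 for skeletal muscle and −0.38 to 1.74 for erythroid markers. Log2 differences ran from −0.34 to 0.066 for epididymal Adipoq, −0.79 to 2.1 for inguinal Ucp1, −0.16 to 0.083 and −0.15 to 0.17 for Impdh1 in epididymal and inguinal adipocytes, and −0.15 to 0.0053 for epididymal Lrrc4.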

Other observations

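The test of the library set in this part was chosen after the result was seen. Tph2 was at most 0.559 FPKM in each white normal-diet library. Ighm, the IgM heavy chain gene, was 510 ± 101 FPKM in epididymal high-fat against 145 ± 11.8 in epididymal normal-diet libraries (log2 1.80, limma adjusted p = 0.0074), and stood at 412 to 595 FPKM in inguinal high-fat libraries, in which Cd79a was low.

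Ribosomal protein genes were lower in inguinal high-fat than normal-diet libraries, with 75 of 87 called lower, 1 higher and a median log2 difference of −1.45, and 76 and 77 lower under TMM factors and quantile normalization. The library set that mitochondrial tRNA separates was tested as a hypothesis, and it is argued against by a median of −1.30 without normal-diet replicate 0, the only inguinal library of the other set. Of the 87, 53 were then called lower, and 1 without normal-diet replicates 0 and 2, at a median of −0.63. These 2 libraries were the richest in lymphocyte markers, of which 13 of 14 were lower on the high-fat diet as well (median −4.15). The median epididymal minus inguinal difference was −0.09 on the normal and 1.44 on the high-fat diet. The cause stays open.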
